A study of Homo sapiens with 10 samples.

How the data were processed

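The series holds 10 arrays of total RNA from HepG2 cultures, 5 in co-culture with THP-1 cells and 5 in single culture. Per the labels, HepG2 cells were seeded at 1.3 and THP-1 cells at 0.65 (in units of 1e5 cells per cm2), THP-1 cells had been treated with 100 nM PMA for 24 h, and RNA was purified on silica columns. A service company carried out the labelling and hybridisation to Affymetrix Clariom S human arrays.

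The authors deposited 1 table of values on a log2 scale, with a column per array. Per the labels, the values came from Expression Console with an analysis of core exons, and the submitters' processing notes also name the Transcriptome Analysis Console. Their versions and the method of background correction and normalization are not given in the sources used here. The log2 base was taken from the range of the values, 2.15 to 18.31. Array medians and quartiles were close to each other, so the values were used as deposited. Means of the positive control rows did separate the groups, at 12.74 to 12.83 on co-culture arrays and 12.88 to 12.93 on single culture arrays. Of 2903 control rows 256 changed (limma adjusted p under 0.05 over the control rows), 0 of them background bins or spikes. Because the highest values exceed the 16 bits of a scanner, differences are those of rescaled values and may not equal the folds in RNA.

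The table had 24351 rows, of which 2903 were control rows and 21448 were not. A table of probe set annotation gave 1 gene symbol for 17709 rows, several for 0, and none for 3739 rows that were not controls. The gene IDs of all 17709 rows were found in a reference gene table, and 0 symbols needed an update. The 3739 rows without a name here were left out of the comparison of named genes. For 20 genes with more than 1 row, the row with the highest mean over all arrays was kept, which left 17687 genes. The genome build was not used here, so no coordinates are given. No filter on dim genes was applied. The 612 negative control rows had a median of 4.43 and a 95th percentile of 8.23 over all arrays, and 9899 genes had a mean below 8.23 in both groups. Per array this percentile ran from 7.92 (single culture replicate 4) to 9.02 (co-culture replicate 2), so a mean near 8.23 is not clearly above or below background.

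Groups came from the treatment label of each array. The main comparison used limma 3.58.1 in R 4.3.3, with a linear model of co-culture against single culture on all 10 arrays, moderated variances, 2-sided tests and Benjamini-Hochberg adjustment over all 17687 genes, at an adjusted p under 0.05. Errors are SDs over 5 arrays or standard errors of the log2 difference from limma. Intervals are 95% intervals from the same model. The 35 gene lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. Member counts are given over all genes tested and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

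The gene lists, the tests of genes and of these lists, all but 3 of the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among genes that passed with no overlap between the groups. It also took AHR, ARNT, AHRR, CYP1A1, CYP1A2, CYP1B1, TIPARP, IL6, CXCL8, IL1B, TNF and CCL2 whether or not they passed. From each list it took up to 4 members, or up to 8 in the AHR target, cytokine, acute-phase and P450 lists, with the largest differences among those that passed, or up to 2 where 0 passed. Last, it took the 8 macrophage markers with the highest mean. This gave 155 measured genes, of which 140 passed, 27 of these with some overlap between the groups. Overlap was judged over all 10 arrays and not within the numbered pairs. Within the pairs, 24 of the 27 changed in 1 direction in all 5, and CYP1A2, ONECUT1 and EGLN3 in 4. AHRR and TNF were not analysed here.

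The labels number the arrays of each group from 1 to 5 and do not say what a number marks, beyond 5 biological replicates per condition. Arrays with the same number deviated from their group means together, with correlations of 0.17, 0.40, 0.30, 0.31 and 0.33 over genes. These were all above 0.1, against at most 0.16 for different numbers, and all 10 arrays correlated best with their own number. The numbers were therefore read as pairing the samples. The main model, fixed beforehand, had no block, so its adjusted p values, the remarks on overlap and the fits without 1 array ignore this pairing. A fit with the replicate number as a block was run as an alternative and gave 3979 changed genes against 3053. No 2 arrays were copies of each other (highest correlation 0.995).

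The analysis was tested on simulated data with 200 changed genes among 17687, over 3 runs. For the comparison of co-culture with single culture it recovered 38.8% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold. False calls made up 5.1% of all calls, and 0 of 20 random lists per run were called. Genes were simulated independently of each other, so this does not test lists of correlated genes, such as the mitosis list (estimated correlation 0.871). The simulations also changed far fewer genes than the 3053 called in the data, so the share recovered may differ there.

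Alternatives were the replicate block, quantile normalization, median centring, filters on the lowest 30% of genes or on genes below the median, an intensity trend with a robust prior, array weights, the mean of a gene's rows, testing every row that was not a control, leaving out each array in turn, and an adjusted p under 0.01. Chosen after the data were examined were a filter on genes below the negative control level in both groups, the estimated correlation together with the replicate block, and gene families defined by shared symbol stems. Splits of the 10 arrays into other groups of 5 were also tested, 100 drawn of the 126 possible.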

Results

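Gene expression was measured on 10 Affymetrix Clariom S human arrays, 5 from HepG2 single culture and 5 from co-culture. HepG2 is an established human liver cancer line that keeps many hepatocyte functions. THP-1 is a human monocytic leukaemia line that takes on macrophage traits when it is differentiated with phorbol 12-myristate 13-acetate (PMA). In co-culture, HepG2 cells spent 24 h near THP-1 cells differentiated in this way without touching them (indirect contact), and in single culture they were kept alone. PMA is given for the co-culture samples only, so effects of PMA and of THP-1 cells cannot be told apart. The labels name both cell types as the source of the co-culture RNA and do not say which cells were lysed. Each group had 5 biological replicates, and the number of arrays limits the precision. The deposited values were on a log2 scale and ran from 2.15 to 18.31, with array medians over the named genes between 7.17 and 7.23. Arrays correlated at 0.989 to 0.995 within a group and at 0.974 to 0.988 between groups. The highest values exceeded 16, the log2 of the largest value a 16-bit scanner gives, so an earlier rescaling is part of every fold given here. The arrays carried no detection calls. A group mean under 8.23, the 95th percentile of the 612 negative control rows, is called below background in the text. For a gene below background in 1 group, a fold is given as "at least", against that level, and for a gene below it in both groups only levels are given. Such a fold rests on the group mean without its spread, so it is not a confidence bound.

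The comparison of co-culture with single culture asked how indirect contact with macrophage-like cells changed expression in HepG2 cultures, with signalling through the aryl hydrocarbon receptor (AHR) and inflammatory cytokines as the study's stated topics. In co-culture the AHR target CYP1A1, the chemokine CXCL8, the growth factor binding protein IGFBP1 and the NF-kB target ICAM1 rose. All 23 genes of DNA replication and 26 of mitosis on the lists tested were lower, and 15 of 18 of cholesterol synthesis, with 3 not passing. These 3 lists passed with camera at a preset correlation but not at an estimated one (adjusted p = 0.11, 0.11 and 0.201). Of 17687 genes tested with limma, 3053 (17.3%) changed at a Benjamini-Hochberg adjusted p under 0.05, 1506 higher and 1547 lower in co-culture. Of these, 1013 rose and 1102 fell by at least 1.5-fold, and 86 rose and 79 fell by at least 4-fold. The 5 values of each group did not overlap for 2494 genes (14.1%), where chance gives 0.794%. The first principal component held 51.5% of the variance and separated the groups. The changed genes included 691 that were below background in both groups.

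Of the 12 genes with the largest rises in log2 value, 9 were below background in single culture, so their order is not an order of folds. CYP1A1 (probe set TC1500010042.hg.1), which encodes a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, rose from 7.10 ± 1.25 to 14.00 ± 1.44 (mean log2 value ± SD, n = 5 in each group here and below; limma adjusted p = 7.89e-06), at least 54.5-fold. VNN1, a pantetheinase that releases vitamin B5 and cysteamine, rose from 5.33 ± 0.40 to 11.53 ± 0.86 (adjusted p = 1.29e-07), at least 9.89-fold. TFF1, a secreted trefoil peptide of mucosal epithelia, rose from 6.63 ± 0.70 to 11.19 ± 1.40, and IGFBP1, a liver-secreted binding protein of insulin-like growth factors, from 13.05 ± 0.83 to 17.31 ± 0.18 (19.1-fold, adjusted p = 8.44e-07). RAB3B, a small GTPase of regulated secretion, rose 14.7-fold, and HAVCR1, a membrane receptor induced in injured kidney epithelium, 12.9-fold (SE of the log2 difference 0.35 and 0.17). G6PC1, the glucose-releasing phosphatase of gluconeogenesis, rose at least 4.79-fold, the water and glycerol channel AQP3 at least 3.31-fold (at least 2.11-fold without co-culture replicate 5), and DEPP1, a FOXO target gene, at least 5.31-fold. GMFG, an actin regulator abundant in blood cells, rose at least 3.13-fold. The mean of TNFSF14, a cytokine of the tumour necrosis factor family, went from 4.92 ± 0.20 to 8.26 ± 0.76, just above background, and that of the transmembrane protein TMEM156 from 4.33 ± 0.33 to 8.20 ± 0.91, below it. As the rule that picked them required, all 12 genes passed with no overlap between the groups, and their adjusted p values ran from 5.5e-08 (HAVCR1) to 0.000786 (G6PC1). Without 1 array at a time each kept its call.

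The largest falls included 8 genes of cell division or DNA synthesis. ERP27, an endoplasmic reticulum protein that binds unfolded polypeptides, fell from 12.55 ± 0.36 to 8.93 ± 0.63 (12.3-fold, adjusted p = 9.2e-07 with limma). KIF20A, a mitotic kinesin, fell 6.59-fold, FOXM1, the transcription factor of late cell cycle genes, 5.96-fold, and TK1, the thymidine kinase of DNA synthesis, 5.93-fold (SE of the log2 difference 0.33, 0.29 and 0.25). CCNB2, a mitotic cyclin, fell 5.74-fold and CDC20, an activator of the anaphase-promoting complex, 5.55-fold. GTSE1, a microtubule-binding protein of dividing cells, fell at least 2.69-fold and BIRC5, survivin of the chromosomal passenger complex, at least 5.93-fold. The mean of LIG1, the ligase that joins Okazaki fragments, went from 7.09 ± 0.24 to 4.54 ± 0.38, below background in both groups. KLB, the co-receptor of the hormones FGF19 and FGF21, fell at least 6.16-fold, the organic anion transporter SLCO4C1 at least 4.64-fold, and AKR1D1, a steroid reductase of bile acid synthesis, at least 1.96-fold. By the same rule the groups did not overlap for any of the 12 genes, and AKR1D1 had the highest adjusted p (0.00152).

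AHR signalling was addressed by the receptor, its partners and its target genes. AHR itself (probe set TC0700006795.hg.1), the ligand-activated transcription factor, rose from 14.25 ± 0.30 to 15.51 ± 0.30 (2.4-fold, limma adjusted p = 0.000132), with all 5 co-culture arrays above all 5 single culture arrays. Of the 16 measured AHR targets, 5 were higher, 0 were lower and 11 did not pass, and the count adjusted over the list alone was also 5. Besides CYP1A1, these were the P450 CYP2S1 (log2 difference 1.52 ± 0.37, SE), and KYNU, a kynurenine pathway enzyme (1.47 ± 0.21). Below background in both groups, the others were the ubiquitin ligase subunit ASB2 (4.82 to 5.89) and CYP1A2, a drug-metabolising P450 close in sequence to CYP1A1 (4.39 to 5.30, adjusted p = 0.0117). The groups overlapped for CYP2S1 and CYP1A2. TIPARP, an AHR feedback regulator, did not pass (log2 difference 0.29, 95% interval -0.01 to 0.58, adjusted p = 0.191), and neither did CYP1B1, a P450 below background in both groups (3.74 and 4.04). Of the 5 measured pathway components only AHR passed (list adjusted p = 0.812, and 1 higher and 1 lower adjusted over the list alone), and ARNT, the receptor's dimerisation partner, had a log2 difference of -0.10 (adjusted p = 0.682). The component list's median was -0.10 and its mean 0.09. AHRR was not analysed here. The target list as a whole did not pass with camera (median log2 difference 0.07, adjusted p = 0.0513, and adjusted p = 0.201 with an estimated correlation). It passed without co-culture replicate 1 (adjusted p = 0.028), co-culture replicate 2 (0.0157) or single culture replicate 1 (0.0407), 3 (0.0479) or 5 (0.0428), and after median centring (0.0444), with array weights (0.0325) among all rows (0.0445) or with fry (0.00453).

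Among secreted cytokines and chemokines, 5 of 25 measured genes were higher in co-culture, 0 were lower and 20 did not pass. CXCL8, the neutrophil chemokine interleukin-8, rose from 7.34 ± 0.75 to 10.31 ± 0.93, at least 4.25-fold (limma adjusted p = 0.000151). CCL20, a chemokine for CCR6-bearing lymphocytes, rose 5.97-fold from 13.17 ± 0.81 to 15.74 ± 0.62, CSF1, the macrophage growth factor, 3.52-fold, and IL32, an inducer of inflammatory cytokines, 2.33-fold. LIF, a cytokine of the interleukin-6 family, passed below background (6.61 to 7.65). IL6 (3.62 and 3.61 in single culture and co-culture), IL1B (4.31 and 4.20) and CCL2 (4.58 and 4.49), a cytokine pair and a monocyte chemokine, did not pass and were below background in both groups. TNF was not analysed here. The list passed with camera (median log2 difference 0.16, adjusted p = 0.031, and adjusted p = 0.181 with an estimated correlation), and its count adjusted over the list alone was also 5. The median is set by the 19 members below background in both groups, and that of the other 6 was 1.52 (camera adjusted p = 0.0028 with such genes left out). The list did not pass without single culture replicate 4 (median 0.09, adjusted p = 0.0641) or after quantile normalization (adjusted p = 0.0549).

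Of 19 NF-kB target genes, 12 were higher, 0 were lower and 7 did not pass (13 higher adjusted over the list alone). ICAM1, the leukocyte adhesion receptor, rose 5.11-fold from 10.67 ± 0.36 to 13.02 ± 0.64 (limma adjusted p = 3.05e-05). NFKB2, an NF-kB subunit, rose 3.08-fold and TNFAIP3, the NF-kB inhibitor A20, 2.87-fold, while the mean of the iron-scavenging lipocalin LCN2 went from 4.86 to 6.90 below background. The list's median log2 difference was 0.72 (camera adjusted p = 3.88e-10, and adjusted p = 0.0609 with an estimated correlation). Beside the cytokine and NF-kB genes, 5 of 32 macrophage and monocyte markers were higher, with a median log2 difference of 0.09 over a list with 28 members below background in both groups and 0.89 over the other 4. The marker list passed with camera (adjusted p = 0.0266, and adjusted p = 0.113 with an estimated correlation). It did not pass without co-culture replicate 1 (0.0672) or after quantile normalization (0.0549).

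**Figure D1:**
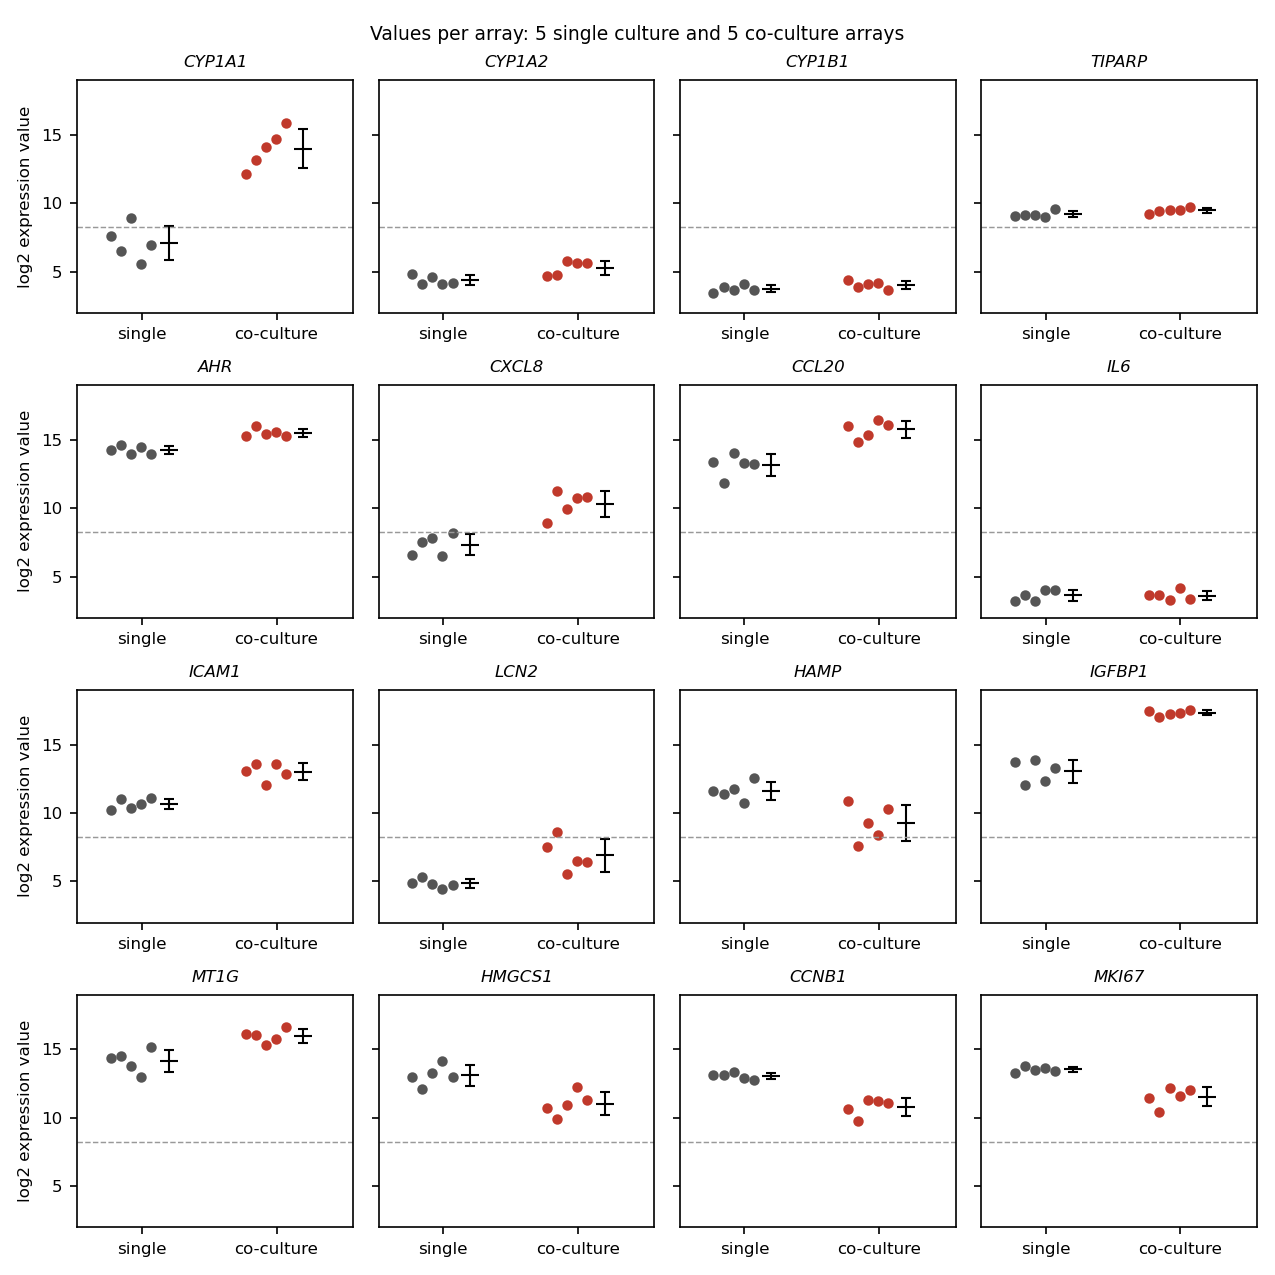
Log2 expression values of 16 genes, 1 panel each, with 1 point per array (5 single culture in grey, 5 co-culture in red), black bars for the mean ± SD of each group and a dashed line at the 95th percentile of the negative controls (8.23). CYP1A1 goes from 7.10 to 14.00 and CXCL8 from 7.34 to 10.31, IL6 stays under 5 in both groups, and CCNB1 and MKI67 are lower on every co-culture array.

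Of 15 receptors, mediators and response genes of interleukin-6 and STAT3 signalling, 6 were higher in co-culture, 0 were lower and 9 did not pass. Adjusted over the list alone 7 were higher, and with the replicate number as a block 8 were higher and 1 lower. IL6R, the ligand-binding receptor chain, rose from 7.95 ± 0.46 to 10.42 ± 0.24, at least 4.59-fold (limma adjusted p = 2.48e-06), and OSMR, the oncostatin M receptor, 4.12-fold. The kinase PIM1, a STAT3 target, rose 2.3-fold with overlap between the groups, and the AP-1 subunit JUNB went from 4.81 to 6.35 below background. The list's median log2 difference was 0.38 (camera adjusted p = 0.000134, and adjusted p = 0.0609 with an estimated correlation). The acute-phase proteins split, 9 of 22 higher and 2 lower, also when adjusted over the list alone. The copper protein ceruloplasmin (CP) rose 3.45-fold, the protease inhibitor SERPINA3 2.5-fold with overlap, the glycoprotein LRG1 at least 2.14-fold, and complement factor CFB 2.14-fold. LBP, which binds bacterial lipopolysaccharide, went from 3.48 to 4.58 below background. The iron hormone hepcidin (HAMP) fell 4.99-fold (adjusted p = 0.00496), with overlap, and haem-binding HPX at least 1.3-fold. The acute-phase list did not pass (median 0.12, adjusted p = 0.0747, and adjusted p = 0.618 with an estimated correlation), but passed without co-culture replicate 2 (0.0399), co-culture replicate 4 (0.0235) or single culture replicate 5 (0.0428). Its median ran from 0.04 to 0.21 as arrays were left out.

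Of 10 plasma proteins that fall in an acute-phase response, SERPINA5, protein C inhibitor, was 2.97-fold lower with overlap between the groups, and AHSG, fetuin-A, 1.33-fold higher (limma adjusted p = 0.0491). AHSG lost its call in 8 of the 10 fits without 1 array, with adjusted p up to 0.122, in the fit without single culture replicate 4. It also lost it after quantile normalization (0.0553) or median centring (0.0674), with array weights (0.0699) and among all rows (0.0537). The list did not pass (adjusted p = 0.276, with 1 higher and 3 lower adjusted over the list alone and 2 higher and 5 lower with the replicate number as a block). Complement and coagulation genes had 6 of 26 higher, 0 lower and 20 not passing. With the replicate number as a block these were 11 higher and 3 lower, and adjusted over the list alone 10 higher and 1 lower. C3, the central complement component, rose 1.54-fold (16.49 ± 0.21 to 17.11 ± 0.18), while SERPING1, the C1 inhibitor, went from 6.27 to 7.70 and the C1 protease C1R from 4.27 to 5.08, both below background and with overlap between the groups. The list passed with camera (median 0.25, adjusted p = 0.0145, and adjusted p = 0.489 with an estimated correlation) but not without co-culture replicate 1 (adjusted p = 0.0754).

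Of 13 genes of antigen presentation on MHC class I, 7 were higher in co-culture, 0 were lower and 6 did not pass (8 higher adjusted over the list alone). TAPBP, the peptide-loading chaperone tapasin, rose 2.73-fold from 11.59 ± 0.41 to 13.04 ± 0.29 (limma adjusted p = 0.00011), B2M, the class I light chain, 1.84-fold, HLA-E, a non-classical class I heavy chain, 1.82-fold, and ERAP1, a peptide-trimming protease, 1.52-fold. The list's median was 0.44 (camera adjusted p = 8.48e-05, and adjusted p = 0.11 with an estimated correlation). HLA genes have near-identical copies, so their values are uncertain. Type I interferon response genes were mixed, with 5 of 23 higher, 2 lower and 16 not passing (10 higher and 3 lower adjusted over the list alone). OAS1, which senses double-stranded RNA, rose from 7.97 ± 0.50 to 10.95 ± 0.45, at least 6.62-fold, IRF9, the DNA-binding subunit of the interferon-activated factor, 2.6-fold, and IFI6, an antiviral membrane protein, 2.15-fold with overlap. IFIT1, which binds foreign RNA caps, was lower below background (5.44 to 4.29). The list passed with camera (median 0.25, adjusted p = 0.0115, and adjusted p = 0.142 with an estimated correlation), and the 8 members not below background in both groups had a median of 0.74 (adjusted p = 0.00852 with such dim genes left out). The 10 members left by the median filter, which does not use the groups, had a median of 0.54 (camera adjusted p = 0.00447). The macrophage and monocyte markers beside these lists had 5 of 32 higher and 0 lower.

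Of 24 immediate-early genes and feedback inhibitors of MAP kinase signalling, 13 were higher, 0 were lower and 11 did not pass (20 higher adjusted over the list alone). The ERK phosphatases DUSP5 and DUSP6 rose at least 2.89-fold and 6.16-fold, DUSP6 from 10.59 ± 0.36 to 13.21 ± 0.20 (limma adjusted p = 3.86e-07). SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose 4.22-fold, and EGR1, a growth-induced transcription factor, at least 2.85-fold with overlap between the groups and no call under an intensity trend (adjusted p = 0.0531). The list's median was 0.72 (camera adjusted p = 2.82e-12, and adjusted p = 0.0609 with an estimated correlation). Among genes of extracellular matrix remodelling and the TGF-beta response, 9 of 25 were higher, 2 were lower and 14 did not pass (11 higher and 2 lower adjusted over the list alone). ITGA2, a collagen receptor subunit, rose 7.41-fold from 11.32 ± 0.42 to 14.21 ± 0.47, TIMP1, an inhibitor of matrix metalloproteinases, 6.94-fold, and CCN1, a matrix-associated signalling protein, 3.79-fold, while the collagenase MMP1 went from 5.31 to 7.21 below background. The list passed with camera (median 0.22, adjusted p = 0.00311, and adjusted p = 0.124 with an estimated correlation), and the 12 members not below background in both groups had a median of 1.09 (adjusted p = 0.00397 with such dim genes left out). The 13 members left by the median filter, which does not use the groups, had a median of 0.92 (camera adjusted p = 0.00269).

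All 26 mitosis genes on the list were lower in co-culture, with a median log2 difference of -2.02 (camera adjusted p = 1.96e-28, and adjusted p = 0.11 with an estimated correlation). KIF20A fell from 11.52 ± 0.19 to 8.80 ± 0.92, BIRC5 from 10.79 ± 0.27 to 8.10 ± 0.91, CCNB2 from 12.13 ± 0.19 to 9.61 ± 1.06 and CDC20 from 13.08 ± 0.19 to 10.61 ± 0.72, with limma adjusted p values from 2.44e-05 (CDC20) to 0.000258 (CCNB2). All 23 S-phase and replication genes were lower (median -1.69, camera adjusted p = 4.39e-24, and adjusted p = 0.11 with an estimated correlation). CDT1, which licenses replication origins, fell at least 1.21-fold, the origin-unwinding subunits GINS1 and GINS2 fell 4.39-fold and 4.29-fold, and RRM2, a subunit of the enzyme that makes deoxyribonucleotides, 4.24-fold from 13.61 ± 0.15 to 11.53 ± 0.67. Of 20 histone genes, which are transcribed mainly during replication, 16 were lower, 0 were higher and 4 did not pass (18 lower adjusted over the list alone). H2BC14 fell by 2.24 (± 0.25, SE) on the log2 scale, H1-5 by 2.11, H2AC4 by 2.00 and H2AC11 by 1.91. The histone list's median was -1.05 (camera adjusted p = 1.93e-13, and adjusted p = 0.11 with an estimated correlation), and near-identical histone copies make single values uncertain. The mitosis and replication counts were the same adjusted over the list alone.

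Of 18 cholesterol synthesis genes, 15 were lower in co-culture, 0 were higher and 3 did not pass (16 lower adjusted over the list alone). IDI1, the isopentenyl diphosphate isomerase, fell 4.39-fold from 13.79 ± 0.79 to 11.66 ± 0.90, and HMGCS1, which makes the precursor of mevalonate, 4.23-fold from 13.11 ± 0.75 to 11.03 ± 0.84 (limma adjusted p = 0.00199 and 0.0016). HSD17B7, a sterol reductase, fell 2.86-fold, and MVD, the mevalonate pathway decarboxylase, 2.75-fold. Of these 4, the groups overlapped for IDI1, HMGCS1 and MVD, each lower in all 5 numbered pairs. The list's median log2 difference was -1.22 (camera adjusted p = 2.06e-10, and adjusted p = 0.201 with an estimated correlation). Of 14 fatty acid and triglyceride synthesis genes, 8 were lower, 0 were higher and 6 did not pass (10 lower adjusted over the list alone). GPAM, the first acyltransferase of glycerolipid synthesis, fell 4.25-fold from 11.42 ± 0.33 to 9.33 ± 0.65, the desaturase FADS2 3.65-fold with overlap (adjusted p = 0.0136, 0.0642 under an intensity trend, and lower in all 5 numbered pairs), the lipid droplet protein PNPLA3 at least 1.41-fold, and DGAT2, which completes triglyceride synthesis, 2.47-fold. That list's median was -0.79 (camera adjusted p = 9.66e-07, and adjusted p = 0.11 with an estimated correlation).

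Genes of fatty acid oxidation moved both ways, 2 of 16 higher and 2 lower (list adjusted p = 0.85, and 3 higher and 2 lower adjusted over the list alone, 4 and 2 with the replicate number as a block). The peroxisomal enzyme EHHADH fell 1.86-fold and the mitochondrial thiolase ACAA2 1.73-fold, with adjusted p = 0.00149 and 0.00038 (limma). The acyl-CoA dehydrogenase ACADVL rose 1.43-fold and lost its call without co-culture replicate 5 (adjusted p = 0.056, with a log2 difference of 0.48 against 0.51), and ACADL went from 5.57 to 6.13 below background, with overlap between the groups and no call without single culture replicate 4 (adjusted p = 0.0504). Of 15 genes of lipoproteins and their export, 3 were higher and 4 lower (3 and 5 adjusted over the list alone). APOC3, an inhibitor of triglyceride clearance, fell 4.19-fold from 13.41 ± 0.56 to 11.34 ± 1.16, LCAT, which esterifies plasma cholesterol, 2.45-fold, and APOH, a phospholipid-binding plasma protein, 1.82-fold, while the lipoprotein component APOC1 rose 1.52-fold with overlap. The list did not pass (adjusted p = 0.592), and its median of 0.08 and mean of -0.24 differed in sign.

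Of 12 genes of gluconeogenesis and insulin-like growth factor binding, 6 were higher, 0 were lower and 6 did not pass (8 higher adjusted over the list alone, 8 higher and 1 lower with the replicate number as a block). Beside IGFBP1 and G6PC1, the binding protein IGFBP3 rose at least 1.8-fold to 9.08 ± 1.14 (limma adjusted p = 9.52e-05). PCK1, the cytosolic enzyme that starts gluconeogenesis from oxaloacetate, rose from 7.10 ± 0.21 to 8.70 ± 0.77, at least 1.39-fold. The list's median was 1.19 (camera adjusted p = 5.22e-05, and adjusted p = 0.0609 with an estimated correlation). In the glycolysis and hypoxia list, 6 of 25 genes were higher, 0 were lower and 19 did not pass, with 12 higher when the replicate number was a block and 8 higher adjusted over the list alone. NDRG1, a stress-induced gene, rose 6.95-fold from 8.41 ± 0.45 to 11.20 ± 0.83, and the vasodilator peptide ADM at least 3.3-fold. P4HA1, a collagen prolyl hydroxylase, rose 1.87-fold with overlap (adjusted p = 0.0288), and the oxygen-sensing hydroxylase EGLN3 passed below background (4.90 to 6.97, adjusted p = 0.0481), also with overlap. P4HA1 lost its call in 6 of the 10 fits without 1 array (adjusted p up to 0.0746, without single culture replicate 4) and EGLN3 in 7 (up to 0.115, without co-culture replicate 1). EGLN3 also lost it under an intensity trend (0.146), after quantile normalization (0.0531) or median centring (0.051) and among all rows (0.0535). The list passed with camera (median 0.41, adjusted p = 6.48e-05, and adjusted p = 0.469 with an estimated correlation), and its median ran from 0.27 to 0.49 as arrays were left out.

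Among P450 enzymes outside the AHR list, 1 of 16 was higher and 3 were lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.898). CYP3A5, a drug-metabolising P450, rose from 7.58 ± 0.53 to 9.83 ± 0.56, at least 3.05-fold (limma adjusted p = 5.54e-05). The fatty acid hydroxylases CYP4F3 (8.06 to 7.13) and CYP4F2 (7.75 to 6.92), close in sequence, were lower below background. CYP27A1, a sterol hydroxylase of bile acid synthesis, fell 1.45-fold and lost its call without single culture replicate 3 (adjusted p = 0.0534). Of 24 conjugating enzymes and transporters, 3 were higher and 6 lower, also adjusted over the list alone (list adjusted p = 0.165). The glucuronosyltransferases UGT2B10 and UGT2B7, members of a family of near-identical genes, fell 3.03-fold and 1.92-fold, the glutathione transferase GSTA2 went from 7.11 to 5.58 below background, and the export pump ABCC3 rose 2.05-fold with overlap. Of 12 hepatocyte transcription factors, 3 were lower and 1 higher, also adjusted over the list alone. CEBPA, a factor of hepatocyte differentiation, fell from 8.80 ± 0.45 to 6.80 ± 0.28, at least 1.49-fold, and the pioneer factor FOXA1 3.4-fold from 12.62 ± 0.18 to 10.86 ± 0.21 (adjusted p = 1.35e-05 and 1.77e-06). ONECUT1, a liver and pancreas regulator, fell 1.8-fold with overlap (adjusted p = 0.0298) and lost its call in 4 of the 10 fits without 1 array (adjusted p up to 0.0832, without single culture replicate 3). NR0B2, the repressor of bile acid synthesis SHP, rose 2.96-fold. That list did not pass with camera (adjusted p = 0.382) but passed with fry (0.0257), and its median of 0.05 and mean of -0.21 differed in sign. For the 6 members not below background in both groups these were -0.50 and -0.51 (adjusted p = 0.228 with such dim genes left out).

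Metallothioneins, the metal-binding proteins, were higher in co-culture, with 7 of the 9 genes of their list higher and 0 lower, also adjusted over the list alone (median 1.60, camera adjusted p = 9.38e-05, and adjusted p = 0.247 with an estimated correlation). MT1G rose 3.52-fold from 14.16 ± 0.81 to 15.98 ± 0.49 (limma adjusted p = 0.00137), MT1H 3.16-fold, MT1M 3.06-fold and MT2A 3.03-fold, and near-identical copies make the single values uncertain. The 2 members that did not pass were zinc transporters. Of 18 NRF2 targets, 1 was higher and 3 lower (3 and 4 adjusted over the list alone, 5 and 5 with the replicate number as a block; list adjusted p = 0.564). The export pump ABCC2 rose 1.9-fold, the pentose phosphate enzyme PGD fell 1.78-fold and glutathione reductase (GSR) 1.55-fold, with overlap for ABCC2 and GSR. The ketosteroid reductase AKR1C2 fell 2.14-fold with overlap (adjusted p = 0.048) and lost its call in 9 of the 10 fits without 1 array, with adjusted p up to 0.117, without single culture replicate 5. It also lost it under an intensity trend (0.117), after quantile normalization (0.0538) and among all rows (0.0533). It was lower in all 5 numbered pairs and passed with the replicate number as a block (adjusted p = 0.0039). Of 15 unfolded protein response genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; list adjusted p = 0.165 with camera and 0.013 with fry). The chaperone partners DNAJB11 and DNAJB9 rose 1.6-fold and 1.5-fold. HERPUD1, of endoplasmic reticulum degradation, rose 1.42-fold and CRELD2, an endoplasmic reticulum stress protein, fell 1.45-fold with overlap. Each of these lost its call in 6 of the 10 fits without 1 array, HERPUD1 with adjusted p up to 0.0934 (without single culture replicate 4), and also after median centring (0.0519) and with array weights (0.051), and CRELD2 up to 0.082 (without co-culture replicate 4).

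Serine synthesis genes were among the falls of the ATF4 and amino acid list, which had 2 of 19 higher and 5 lower (3 and 5 adjusted over the list alone). PHGDH, the first enzyme of serine synthesis, fell 3.52-fold from 12.43 ± 0.48 to 10.61 ± 0.74 (limma adjusted p = 0.000789), PSAT1, the next enzyme, 2.2-fold, and the stress-induced regulator NUPR1 3.22-fold with overlap, while the lipoprotein receptor VLDLR passed below background (6.43 to 7.61). The list did not pass (adjusted p = 0.284) but did without co-culture replicate 5 (0.0256). Of 15 p53 targets, 1 was higher and 4 lower (1 and 5 adjusted over the list alone). GDF15, a stress-induced cytokine, rose 3.09-fold, while SESN1, a regulator of nutrient signalling, fell 2.87-fold, AEN, a nuclease of apoptosis, 1.51-fold with overlap, and BAX, a pore-forming apoptosis protein, 1.4-fold. The list did not pass with camera (median -0.36, adjusted p = 0.0747, and adjusted p = 0.261 with an estimated correlation) but did without single culture replicate 3 (0.0384) and with fry (0.00608). Of 14 iron-handling genes, 1 was higher and 3 lower (1 and 4 adjusted over the list alone, 2 and 6 with the replicate number as a block). Besides HAMP and CP, these were 2 genes that act in or respond to the BMP pathway that controls hepcidin, SMAD7 (2.06-fold lower) and ID1 (1.5-fold lower). The list did not pass (adjusted p = 0.141) but did without co-culture replicate 5 (0.0481).

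Markers of macrophages and monocytes, the other cell type in the co-culture, had 5 of 32 higher, 0 lower and 27 not passing, also adjusted over the list alone, and 8 higher with the replicate number as a block. The lysosomal protease CTSS rose from 5.46 ± 0.59 to 8.40 ± 0.17, just above background (limma adjusted p = 1.77e-06). Lysozyme (LYZ) rose 1.88-fold from 16.45 ± 0.31 to 17.36 ± 0.16, so its signal was already high in single culture, and the lysosomal protein CD68 1.83-fold from 10.09 ± 0.41 to 10.96 ± 0.18. The Fc receptor genes FCER1G (5.18 to 6.36) and FCGR2A (5.51 to 5.99) passed below background. Of the 8 markers with the highest mean, CD74, the MHC class II chaperone, did not pass (11.64 and 12.23, adjusted p = 0.175, and adjusted p = 0.00394 with the block). Neither did the myeloid growth factor receptor CSF1R (7.42 and 7.78, adjusted p = 0.0533), the calcium-binding AIF1 (6.81 and 7.43, 0.163), the signalling adaptor TYROBP (6.69 and 7.09) or the myeloid transcription factor SPI1 (7.30 and 7.21). CSF1R passed with the block (0.033), without co-culture replicate 4 (0.0461) and without single culture replicate 3 (0.0481), and AIF1 with the block (0.0271) and without co-culture replicate 5 (0.0343). The list passed with camera (median 0.09, adjusted p = 0.0266, and adjusted p = 0.113 with an estimated correlation) but not without co-culture replicate 1 (adjusted p = 0.0672) or after quantile normalization (0.0549). The 4 markers not below background in both groups, CTSS, LYZ, CD68 and CD74, had a median of 0.89, and the 5 left by the median filter one of 0.59 (adjusted p = 0.0422).

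**Figure D2:**
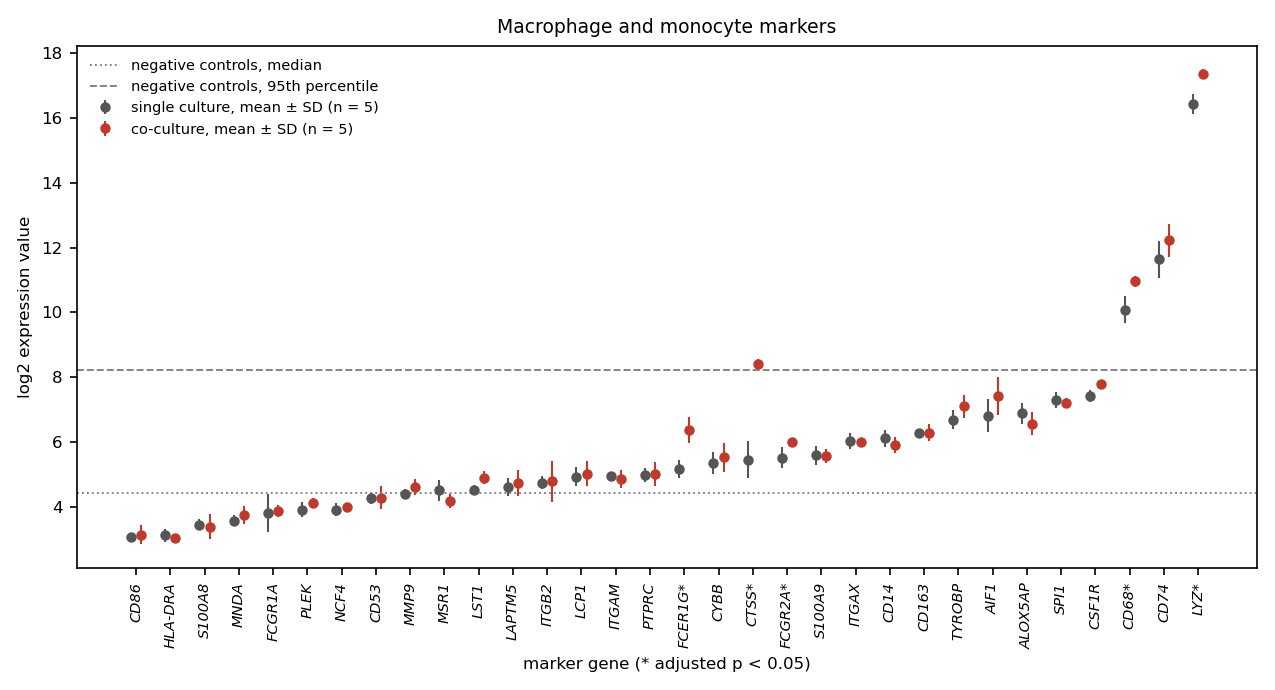
Mean log2 expression value ± SD (n = 5) of 32 macrophage and monocyte markers in single culture (grey) and co-culture (red), ordered by the single culture mean, with the median (4.43, dotted) and 95th percentile (8.23, dashed) of the negative controls. Of the 29 markers below the dashed line in single culture, CTSS is the 1 that lies above it in co-culture, and LYZ is above 16 in both groups.

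The lists of other cell markers and of broadly used genes did not pass. Of 14 hepatocyte-lineage markers, APOH was lower and AHSG higher (0 higher and 1 lower adjusted over the list alone, 3 higher and 5 lower with the replicate number as a block; median -0.26, list adjusted p = 0.592). Of 14 fibroblast and endothelial markers, smooth muscle actin (ACTA2) fell 1.8-fold with overlap, and the endothelial clotting protein VWF passed below background (6.17 to 6.69), with the same count adjusted over the list alone (list adjusted p = 0.898). None of 12 cytosolic ribosomal protein genes passed (median -0.02, list adjusted p = 0.602), and RPS19 and RPS6 had the largest differences, -0.19 and -0.10. Among 20 nuclear-encoded genes of the mitochondrial respiratory chain 0 passed (median -0.06, list adjusted p = 0.673), and COX4I1 and SDHA had log2 differences of 0.33 and -0.23. In total 17 of the 35 lists passed with camera at a preset correlation, 12 higher and 5 lower. With an estimated correlation 0 lists passed, although 12 had an unadjusted p under 0.05, and with limma's fry, which tests a list without comparing it with other genes, 19 passed.

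**Figure D3:**
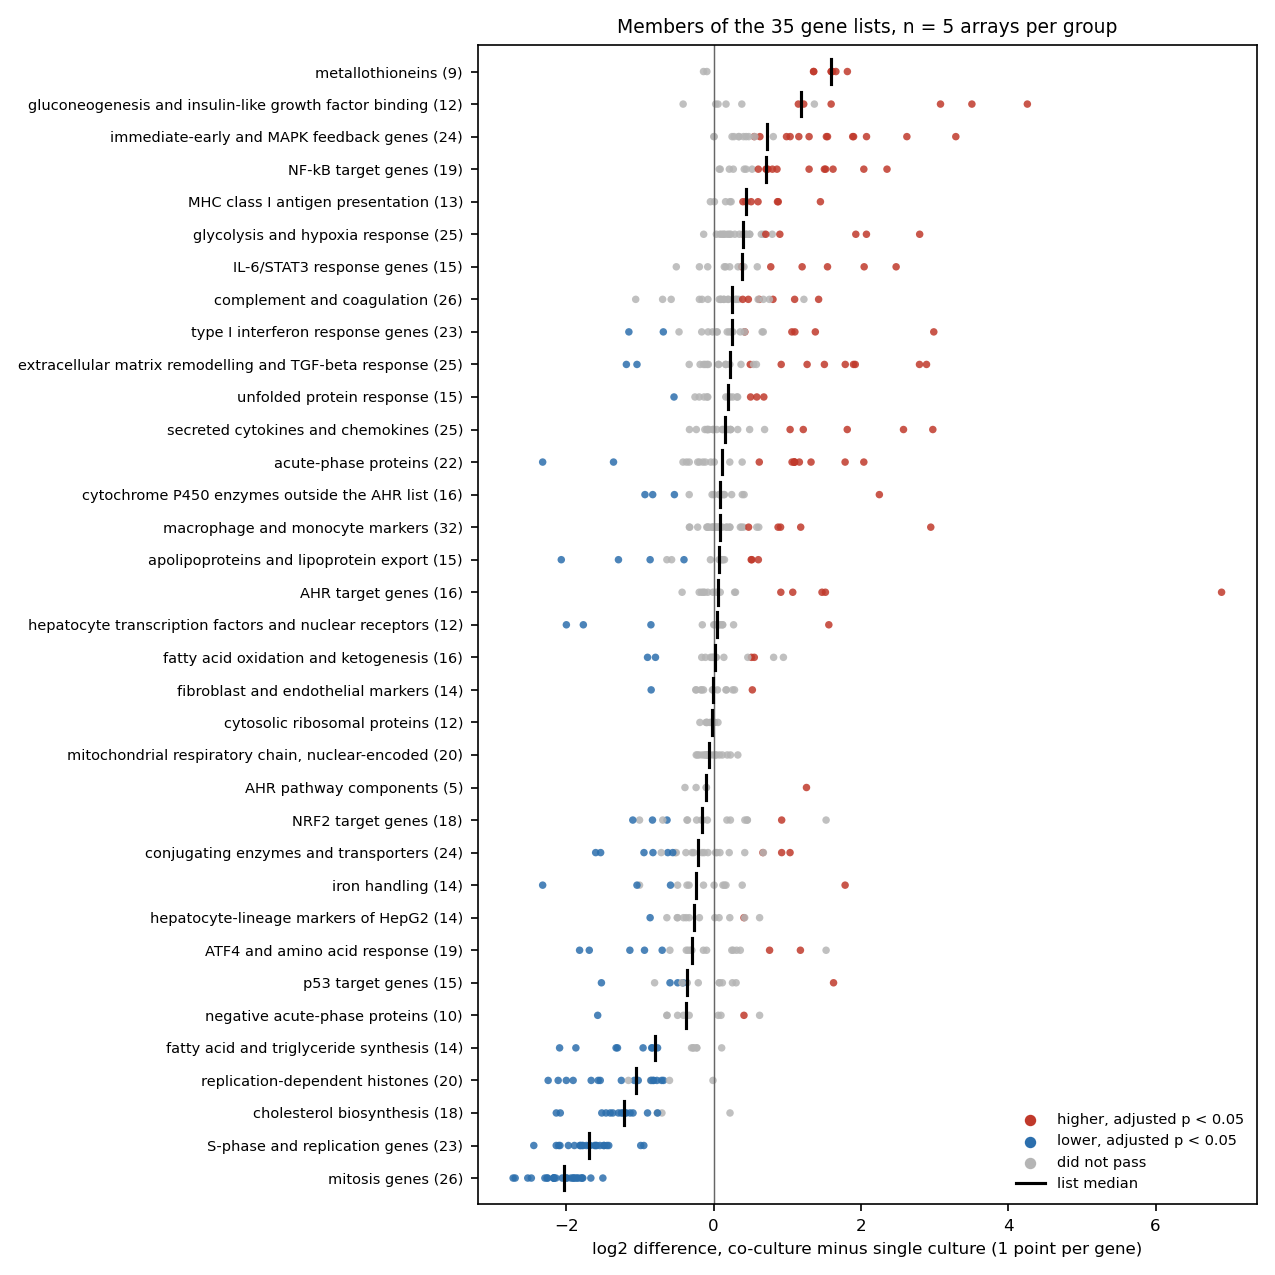
Log2 difference (co-culture minus single culture, n = 5 arrays each) of every measured member of the 35 gene lists, 1 point per gene, red or blue where the gene was higher or lower at adjusted p under 0.05 and grey where it did not pass, with a black bar at each list's median. The medians run from -2.02 (mitosis genes) to 1.60 (metallothioneins), and CYP1A1, below background in single culture, is drawn at 6.89, a difference of deposited values.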

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

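Each group of 5 values of the named genes was tested with Dixon's ratio. Of 310 groups, 22 had an array far from the other 4, where chance gives about 1 in 20 (5%), or 15.5 groups. Genes that vary together can flag the same array, so the number that chance gives is itself uncertain. Chance alone can therefore account for most of these values, and no explanation was tested.

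By this test, single culture replicate 5 lay far above the other 4 for 5 genes. It stood at 13.93 for the ketosteroid reductase AKR1C2 (next value 13.15), at 9.72 for hemopexin (HPX, 8.54), at 13.25 for PHGDH (12.41) and 15.87 for PSAT1 (15.15) of serine synthesis, and at 9.58 for the AHR feedback gene TIPARP (9.16). Also by this test, single culture replicate 3 stood apart as the highest for the peptide hormone ADM at 8.82 (next 7.92), for the apolipoprotein APOC3 at 14.38 (13.35) and for the hydroxylase EGLN3 at 5.97 (4.81), and lowest for TMEM156 at 3.75 (4.41). Single culture replicate 4 was lowest for HLA-E at 8.60 (8.96) and for PCK1 at 6.74 (7.15), and single culture replicate 1 for LIF at 6.02 (6.65).

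By the same test, co-culture replicate 2 stood apart as the lowest for the mitotic genes CCNB2 at 7.73 (next 9.90) and CDC20 at 9.33 (10.73) and for the sterol hydroxylase CYP27A1 at 12.62 (12.96). It was highest for IRF9 at 10.81 (10.30) and for NFKB2 at 11.05 (10.69). Co-culture replicate 1 was highest for ERP27 at 10.02 (8.79) and NDRG1 at 12.68 (10.90), and lowest for the interleukin-6 receptor IL6R at 9.99 (10.47) and for VNN1 at 10.02 (11.74). Co-culture replicate 5 was highest for the stress regulator NUPR1 at 11.15 (9.67).

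Rows without a gene name here were not part of the comparison of named genes. When every row that was not a control was tested, 281 of the 3739 such rows changed, 129 higher and 152 lower in co-culture.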

How the results depend on the processing

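The filter on genes below the negative control level and the estimated correlation with the replicate block were chosen after the data were examined, the other alternatives before. Against 3053 changed genes, the replicate block gave 3979 (2011 higher and 1968 lower, 3047 of the 3053 shared), quantile normalization 3104, median centring 3069, the 30% and median filters 3210 and 2918, the negative control filter 2816, the intensity trend 3094, array weights 3150, mean rows 3058 and all rows 3329. Leaving out 1 array gave 2580 to 3059 genes and 16 to 19 of the 35 lists against 17. At an adjusted p under 0.01 the counts fell to 1860 genes, 883 higher and 977 lower, by construction of the threshold. With an estimated correlation 0 lists passed, and 0 with the replicate block added, against 12 at an unadjusted p under 0.05 without the block and 19 with fry. Of 140 named genes that passed, 128 passed under every alternative that tested them, 0 changed direction and 10 lost their call without 1 array (each passed with the block, at 0.00114 to 0.0188), of which AHSG, AKR1C2, EGLN3 and HERPUD1 also lost it under 2 to 4 other alternatives, while EGR1 and FADS2 lost it with the intensity trend alone. Most named genes were picked for the largest differences among genes that passed, so these counts do not describe all 3053 calls. The block added AIF1, CD74 and CSF1R and changed no other call of a named gene or list with the preset correlation. CSF1R also passed after the 30% (adjusted p = 0.0388) and median filters (0.0286). The AHR target list, at 0.0513, ranged from 0.00453 with fry to 0.372 with the estimated correlation and the block. Of the 17 lists, 14 passed under every alternative with the preset correlation, and fry did not call the complement (0.0793) or glycolysis (0.0606) lists but called those of AHR targets, p53 targets (0.00608), the unfolded protein response (0.013) and hepatocyte transcription factors (0.0257). Leaving out genes below the negative control level in both groups moved some list medians by over 1.5 times, among the lists that passed those of cytokines (0.16 to 1.52), matrix genes (0.22 to 1.09), interferon response genes (0.25 to 0.74) and macrophage markers (0.09 to 0.89, with too few members left to test). This filter also keeps genes that crossed that level in 1 group. Signal over background limits the folds of dim genes, with 9899 of 17687 genes below it in both groups. In simulations with 200 changed genes, far fewer than in the data, 38.8% of 1.5-fold changes were found.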

Other observations

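The gene families, and the tests of dilution, p53, cell cycle and AHR target explanations, were chosen after the results were seen, and the test of THP-1 RNA and the splits of the samples before. Gene families were formed from symbols that share a letter stem, with at least 8 members measured, and 330 were tested with camera. At adjusted p under 0.05, 4 families were higher and 7 lower, and with an estimated correlation 0 passed (adjusted p from 0.821 to 0.837). Nucleoporins (NUP), which build the nuclear pore, had 15 of 20 members lower and 0 higher in co-culture (median log2 difference -0.55, adjusted p = 2.74e-09). Centrosomal proteins (CEP) had 18 of 36 lower and 1 higher (-0.37, 7.74e-07), and the RNA-binding LSM proteins 7 of 12 lower (-0.60, 0.000714). The RNA exosome subunits (EXOSC) had 5 of 9 lower (-0.42, 0.0255), and DNA repair genes of the RAD family 6 of 18 lower (-0.21, 0.0255). Aldehyde dehydrogenases (ALDH) had 7 of 19 lower and 1 higher (-0.25, 0.0399). The replicative helicase family MCM, 9 of 11 lower (-1.60, 2.11e-08), shares 7 members with a list of the report, as the MT family does (11 of 13 higher, 1.44, 1.21e-07). Kruppel-like transcription factors (KLF) had 5 of 16 higher and 0 lower (0.34, 0.0102), and the membrane fusion syntaxins (STX) 4 of 16 higher (0.34, 0.0495). The NBPF genes, near-identical copies of each other, had 5 of 12 higher (0.43, 0.0255), so their values are uncertain.

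The count of 3053 changed genes was set against other splits of the 10 arrays into 5 and 5. Of 100 splits drawn from 126, 1 gave as many genes, the real one, and the highest other split gave 1 gene. Every other split mixes the groups, which widens the spread on each side, so low counts there are partly built in. The splits also cannot tell co-culture from another difference between the groups. Of the 13 splits drawn that part all 5 numbered pairs, the highest other gave 0 genes.

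The lower expression of replication and mitosis genes was set against 3 explanations. Dilution of HepG2 RNA by RNA of other cells was predicted to lower other genes of the same brightness too. The 5698 genes at the single culture level of the mitosis genes (9.34 to 16.2) had a median log2 difference of -0.046. The deposited arrays had close medians, which keeps the median of so many genes from moving, so this test cannot decide on dilution. It shows only that most genes of that brightness did not share the fall. Dilution would also lower the 14 hepatocyte-lineage markers, none below background in both groups, by as much as the mitosis genes (median -2.02). Their median was -0.26 (-0.43 to -0.08 as arrays were left out), with 1 higher and 1 lower, or 3 and 5 with the replicate number as a block. These values argue against dilution as the source of a fall of that size, and a smaller dilution stays open. Activation of p53 would raise its direct target MDM2, whose upper 95% bound was 0.085. Of 15 p53 targets 4 were lower, 1 (GDF15) was higher and 10 did not pass, and the list did not pass with camera (adjusted p = 0.0747). Both the bound and the counts argue against p53 activation, though the counts were known when this test was chosen. For a smaller share of HepG2 cells in the cell cycle, the lowest share of members called lower among the replication, mitosis and histone lists was 80%, but these lists show the pattern itself, so this decides nothing. Cell numbers and division were not analysed here, so slower division, fewer dividing cells and other effects of the co-culture cannot be told apart.

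The rise of immune and inflammatory genes was set against RNA of THP-1 cells in the co-culture samples, through 31 macrophage and monocyte markers that are on none of the cytokine, NF-kB and acute-phase lists. Their median log2 difference was 0.099, with 5 higher and 0 lower, and of the 5 markers named in advance lysozyme passed, while PTPRC (0.03), CD53 (0.02), LAPTM5 (0.12) and TYROBP (0.41) did not. With the replicate number as a block, 8 markers of the whole list were higher and 0 lower, CD74, AIF1 and CSF1R among them. Of 28 markers below background in single culture, 3 were higher, 1 of them above background in co-culture, and their median was 0.073, while the 4 markers not below background in both groups had a median of 0.89. The 3 markers above background in single culture (LYZ at 16.45, CD74 at 11.64 and CD68 at 10.09) give a signal without THP-1 cells, and the dim others exclude nothing, so a share of THP-1 RNA and a rise in HepG2 cells cannot be told apart here. The indirect contact named in the labels would limit, but not rule out, such carry-over.

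The large rise of CYP1A1 beside 11 AHR targets that did not pass was set against limits of the array and a small general rise. Of these targets, 5 (TIPARP, NQO1, SLC7A5, NFE2L2 and, at 8.25 just above background, CYP2W1) had an upper 95% bound under 1 on the log2 scale, which argues against the array's range as the reason for them, also for the bright NQO1 (15.29, upper bound 0.204), since 19 genes above 15.23 in single culture passed as higher. The other 6 lay below background in both groups, so for these a rise that stays below background and no change cannot be told apart. Without CYP1A1 the other 15 members had a directional fry p of 0.00972 with 4 higher, but a median of 0.04 that ran from -0.006 to 0.094 as arrays were left out, so a small general rise may be present and was not decided by the test. The difference between the groups, which covers the THP-1 cells, all that they release and the PMA they were treated with, stays open as the source of the CYP1A1 change.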
